A study of Drosophila melanogaster with 18 samples.

How the data were processed

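RNA was measured by sequencing in 18 libraries, 3 in each of 6 groups: sorted neurons of third-instar larvae and of P14 pupae with and without shep RNAi, and BG3 cells after dsRNA against shep or GFP. The deposited values were raw whole-number read counts per gene, which per the submitters' processing notes came from reads trimmed with cutadapt 1.10, aligned to dm6 with HISAT2 2.0.4 and counted with featureCounts 1.5.0-p3. The annotation release, the strand setting and the handling of multi-mapping reads were not given in the sources used here, so counts of overlapping genes and of near-identical copies are uncertain. The table held 17402 genes, of which 2102 had no count in any library. Symbols and coordinates of 17210 genes came from Ensembl release 115, and the other 192 are given by identifier. All 18 columns were matched to a group by their titles.

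Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, libraries were scaled by TMM, and quasi-likelihood models with robust estimation were fitted to group means. The 12 neuron libraries were fitted together (8 residual degrees of freedom) and the 6 BG3 libraries on their own (4 residual degrees of freedom). The comparisons were shep RNAi against control in pupal and in larval neurons, the difference between these responses, pupal against larval control neurons, and shep against GFP dsRNA in BG3 cells. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The p values measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures or groups of animals.

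These comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took shep, then for each comparison the 10 largest rises and the 10 largest falls among called genes with non-overlapping replicates and a mean of at least 5 CPM. It also took up to 4 members with the smallest p of each list discussed, genes called in the same direction in all 3 knockdown comparisons, and the check genes Dcr-2, elav, repo, roX1 and roX2. The 35 lists covered neuronal function, metabolism and protein synthesis, development and chromatin, stress and cell death, and markers of other cell types. In them 31 entries were matched by a synonym and 34 matched no gene and were dropped. Lists with at least 3 tested members were tested with camera and fry (limma 3.58.1) on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated one, and adjusted over the lists of a comparison.

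Overlaps of calls were tested with Fisher's exact test over genes tested in both comparisons, adjusted over 12 tests. Chromosome arms were tested in the same way over 60 tests. Neighbouring calls and gene lengths were set against 10000 permutations or random sets, the latter matched on expression. The relation of the RNAi response to development was set beside 50 simulated draws without an RNAi effect. In each draw all 12 neuron libraries, controls included, were redrawn, with the RNAi groups at the control means of their stage. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

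The steps were tested on simulated data with 200 changed genes, 50 at each fold. Of genes changed 2-fold, 60% were called in the pupal, 84% in the larval, 64% in the difference, 66% in the stage and 88% in the BG3 comparison, and at 1.25-fold 12%, 26%, 4%, 18% and 26%. False calls made up 8.11%, 4.96%, 6.25%, 5.83% and 9.49% of the calls.

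Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts and a filter of 1 CPM in 3 libraries. Further ones were replicate number as a block, an adjusted p under 0.01 and a minimum of 2-fold. Other sets of libraries were also fitted, and each library was left out in turn. DESeq2 was run without the filter on low counts, so its results do not separate the tool from the filter. The rest were added after seeing the data: removal of the trend with exonic length in each library (lowess, span 0.3), removal of mitochondrial and rRNA genes, and thinning of the BG3 libraries to equal depth.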

Results

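To follow the transcriptional response of neurons to reduced shep, RNA was sequenced from 18 Drosophila melanogaster libraries in 6 groups of 3. shep (alan shepard) encodes an RNA-binding protein that also affects the activity of chromatin insulators. Neurons were sorted by their elav-driven membrane GFP from third-larval-instar and P14 (late pupal) animals, each with or without a shep RNAi transgene. All neuron groups carried Dcr-2, which boosts RNAi. BG3 cells, a line derived from the larval central nervous system, were treated with double-stranded RNA (dsRNA) against shep or, as control, against GFP. Total counts were 7392299 to 10607171 in pupal RNAi, 8548493 to 9445025 in pupal control, 9134690 to 10793289 in larval RNAi and 9984725 to 12910603 in larval control libraries. They were lower in BG3 cells, at 3141100 to 3203392 with GFP dsRNA and 3651214 to 5081610 with shep dsRNA, so that every shep dsRNA library was deeper than every control. Stage separated the neuron libraries along a first principal component holding 93.2% of the variance, against 31.2% for the first component of the BG3 libraries.

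The targeted gene was examined first. shep (FBgn0052423, chromosome arm 3L from 5155821 to 5277944 of dm6) was lower in all 9 knockdown libraries than in the matching controls. Its level in CPM (counts scaled to the library total with TMM factors) fell from 1878 ± 186 to 993 ± 134 in pupal neurons (SD, n = 3 each), a log2 fold change of -0.92 (SE 0.10, edgeR adjusted p = 3.70e-06). In larval neurons it fell from 1312 ± 103 to 484 ± 24.1 CPM (log2 fold change -1.44, SE 0.11, edgeR adjusted p = 4.93e-09). In BG3 cells it fell from 451 ± 26.4 to 213 ± 29.7 CPM (log2 fold change -1.08, SE 0.09, edgeR adjusted p = 1.26e-06). These were reductions of 47.1%, 63.1% and 52.7%, each with an exact 2-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The pupal minus larval difference in the shep log2 fold change was 0.52 (SE 0.15, edgeR adjusted p = 0.141). Levels of Dcr-2, of the neuronal gene elav and of the glial gene repo did not pass the test on knockdown in any of the 3 settings, nor did the dosage compensation RNA roX1 in neurons or roX2 in BG3 cells.

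**Figure D1:**
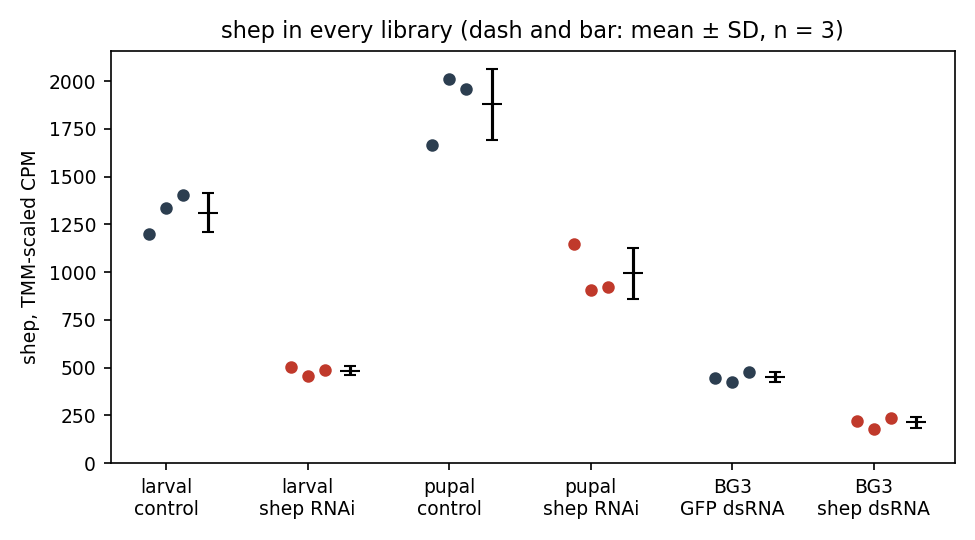
shep in each library, in TMM-scaled CPM on a linear axis from 0; points are libraries, and the dash and bar beside them are the mean and SD of the 3. Knockdown libraries (red) lie below the matching controls (dark) in larval neurons (484 against 1312 CPM), pupal neurons (993 against 1878 CPM) and BG3 cells (213 against 451 CPM).

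To identify genes that responded to shep RNAi in pupal neurons, RNAi and control libraries were compared. The largest rise was of daw (FBgn0031461, arm 2L from 2805261 to 2812376), which encodes an activin-type ligand. Its counts were 1, 0 and 5 in the control libraries and 322, 408 and 279 in the RNAi libraries, or 48.5 ± 7.93 CPM (SD, n = 3; log2 fold change 7.37, SE 0.28). Other rises included pdgy (1.39), an acyl-CoA synthetase gene, the branched-chain ketoacid dehydrogenase subunit gene BckdhB (1.38), the myosin gene Myo28B1 (1.17), the actin-regulating gene sals (1.09) and Aasdh (1.03). CG12716 (2.20) and asRNA:CR43152 (2.16), which lie beside each other on X, also rose. The calls of asRNA:CR43152 and Myo28B1 did not pass with DESeq2. Serinc, a serine incorporator gene, fell from 299 ± 19.0 to 148 ± 9.05 CPM (log2 fold change -1.01, SE 0.07). The ubiquitin ligase subunit gene Roc2 fell from 9.31 ± 1.31 to 4.64 ± 0.53 CPM, and the neuropeptide precursor gene Nplp1 (-0.97), the GABA transporter gene Gat (-0.91) and the DNA repair gene Ogg1 (-0.91) fell too. Of 8784 genes tested, 672 passed an edgeR adjusted p of 0.05, with 306 higher and 366 lower on RNAi. Of all tested genes, 24.5% had no overlap between the groups (chance gives 10%). Changes were mostly modest, with a median absolute log2 fold change of 0.45 among the calls and with 50 rises and 18 falls of at least 2-fold. Fewer genes were called without RNAi replicate 1 (319, 119 higher and 200 lower), control replicate 1 (408, 111 higher and 297 lower) or control replicate 3 (359, 121 higher and 238 lower). Gat was not called without RNAi replicate 3 or control replicate 3, nor was Ogg1 without RNAi replicate 2 or control replicate 3.

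Genes for protein synthesis and energy metabolism were lower in shep RNAi pupal neurons. Of 77 ribosomal protein genes, 40 fell (56 adjusted over the list alone), with a list median of -0.33 and with RpL41 (-0.72), RpL28 (-0.64), RpL17 (-0.59) and RpL8 (-0.59) at the smallest p values (camera adjusted p = 6.18e-22, but adjusted p = 0.209 with an estimated correlation). Of 73 nuclear genes for oxidative phosphorylation, 20 fell (30 adjusted over the list alone), including blw (-0.82), which encodes an ATP synthase subunit, UQCR-C1 (-0.62), COX8 (-0.61) and ND-42 (-0.59). The set passed (camera adjusted p = 1.03e-09, but adjusted p = 0.209 with an estimated correlation), and 12 were called lower with the gene length trend removed, where the median went from -0.20 to -0.16. Of 15 glycolysis genes 8 fell (9 lower and 1 higher adjusted over the list alone), among them Gapdh2 (-0.59), PyK (-0.51), Pgk (-0.47) and Tpi (-0.36) (camera adjusted p = 0.00222, but adjusted p = 0.369 with an estimated correlation).

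Genes of neurotransmission moved in both directions. Of 33 synaptic vesicle and active zone genes, 14 fell and 1 rose (17 and 1 adjusted over the list alone). The falls included the Sec1/Munc18 gene Rop (-0.85), the NSF gene comt (-0.64), the SNARE gene Snap25 (-0.54) and the dynamin gene shi (-0.54) (camera adjusted p = 5.60e-06, but adjusted p = 0.209 with an estimated correlation). Of 17 transmitter synthesis and transport genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone), and the falls spanned cholinergic, glutamatergic and GABAergic genes: ChAT (-0.81), VGlut (-0.65), Gad1 (-0.63) and VAChT (-0.57). The list passed (camera adjusted p = 0.00719, but adjusted p = 0.369 with an estimated correlation). Of 18 neuropeptide genes 5 fell (8 adjusted over the list alone), among them Nplp1, Dh31 (-0.67) and Tk (-0.55). The list passed (camera adjusted p = 0.00593, but adjusted p = 0.209 with an estimated correlation, 0.0576 without control replicate 2, and 0.133 with a median of -0.08, from -0.48, without a filter on low counts). Of 41 transmitter receptor genes 4 rose (5 adjusted over the list alone), led by nAChRalpha1 (0.51). The list passed (camera adjusted p = 0.0101, but adjusted p = 0.536 with an estimated correlation, 0.0683 without control replicate 1, 0.149 with the gene length trend removed and 0.0530 without a filter on low counts).

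Some genes of the cell surface and of developmental timing rose. Of 62 axon guidance and adhesion genes, 11 rose and 3 fell (13 and 3 adjusted over the list alone), with Lac (0.86), NetA (0.70) and rst (0.58) higher and the netrin receptor gene unc-5 (-0.42) lower. The list passed (camera adjusted p = 0.00152, but adjusted p = 0.262 with an estimated correlation and 0.378 with the gene length trend removed). Of 20 temporal identity genes 3 rose (5 adjusted over the list alone), including the ecdysone-responsive transcription factor genes br (0.79) and Eip93F (0.52). The list passed (camera adjusted p = 0.0143, but adjusted p = 0.209 with an estimated correlation, 0.0621 without RNAi replicate 3, 0.0559 without control replicate 1 and 0.0631 without a filter on low counts). Of 35 ecdysone response and remodelling genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone); br and Eip93F are members, and the fall was of Eip63F-1 (-0.43). That list passed narrowly (camera adjusted p = 0.0430, but adjusted p = 0.482 with an estimated correlation) and did not pass without RNAi replicate 1 (0.0849), RNAi replicate 2 (0.0793), control replicate 1 (0.226) or larval control replicate 1 (0.0524), with the gene length trend removed (0.199) or without a filter on low counts (0.0764). Among lists of other cell types, the markers of muscle passed with 2 of 14 higher (2 adjusted over the list alone), Tm1 (0.37) and sls (2.10) (camera adjusted p = 0.0469, but adjusted p = 0.310 with an estimated correlation). The list passed in only 1 of the 12 fits without 1 library (pupal control replicate 2), and neither with the gene length trend removed (0.0746) nor without a filter on low counts (0.0983). sls was lost in 10 of those 12 fits and with DESeq2 and limma-voom, and Tm1 without pupal control replicate 1 or 3. By camera, markers of glia (adjusted p = 0.173), hemocytes (adjusted p = 0.820), fat body (adjusted p = 0.0920), photoreceptors (adjusted p = 0.888), neuroblasts (adjusted p = 0.475), and epidermis and trachea (adjusted p = 0.173) did not pass.

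**Figure D2:**
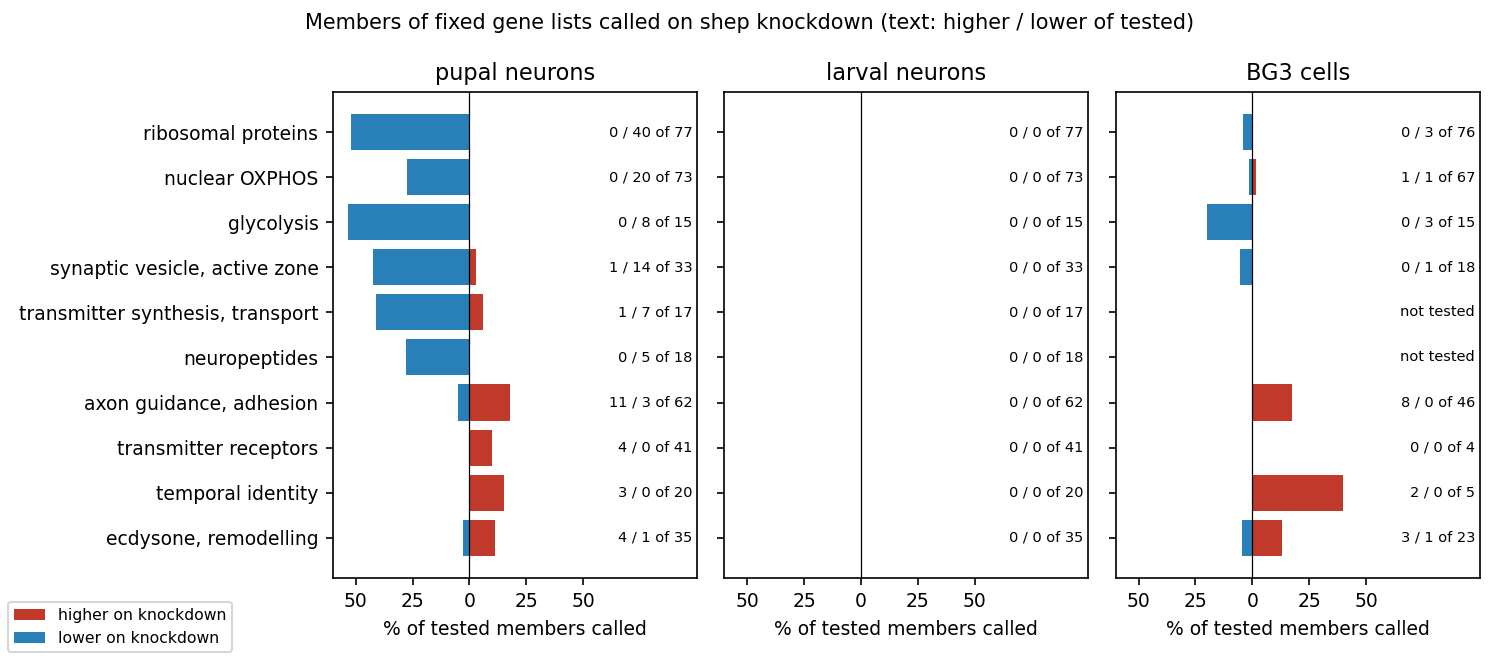
Share of the tested members of 10 gene lists called higher (red, right) or lower (blue, left) on shep knockdown by edgeR at an adjusted p of 0.05, in percent, with the counts printed as higher / lower of tested. Ribosomal protein genes show 40 of 77 lower in pupal neurons, 0 of 77 called in larval neurons and 3 of 76 lower in BG3 cells.

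In larval neurons the same comparison called few genes. daw rose again, from counts of 2, 3 and 2 in the control libraries to 1038, 857 and 802 in the RNAi libraries, or 71.1 ± 3.24 CPM (SD, n = 3; log2 fold change 8.70, SE 0.24, edgeR adjusted p = 5.47e-18). The unconventional myosin gene dachs fell from 10.2 ± 2.15 to 1.69 ± 0.40 CPM (log2 fold change -2.56, SE 0.27, edgeR adjusted p = 4.91e-06), and the receptor kinase gene Nrk fell by 0.51 on the log2 scale (SE 0.08). bark (0.84), mt:ND2 (0.72), mt:ATPase6 (0.53), the neurogenesis gene sca (0.52), the eye colour gene w (0.46) and the acetyl-CoA carboxylase gene ACC (0.37) rose. Drep3 (-0.73), the copper chaperone gene Atox1 (-0.68) and frj (-0.60) fell. w was not called in pupal neurons (0.13, edgeR adjusted p = 0.461) and had no count in BG3 cells. Gene counts cannot tell reads of the endogenous w gene from those of a transgene copy, if one was carried. Of 8784 genes tested, 32 passed, with 15 higher and 17 lower, and 763 had an unadjusted p under 0.05. Of the 20 genes named by rule, 4 (daw, dachs, shep and Nrk) were called in every fit without 1 library, and each of the others was lost in at least 1. The count fell to 10 without larval RNAi replicate 1, 19 without larval RNAi replicate 2 and 20 without larval control replicate 3, and rose to 52 and 50 without pupal control replicates 1 and 2.

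No list had more than 2 members called in larval neurons. Of 16 genes of the mitochondrial genome 2 rose, mt:ND2 and mt:ATPase6 (3 adjusted over the list alone; camera adjusted p = 1.80e-05, but adjusted p = 0.541 with an estimated correlation). Of 62 axon guidance and adhesion genes 0 passed edgeR's test, with 9 higher at an unadjusted p under 0.05 and 1 called by each of DESeq2 and limma-voom (1 adjusted over the list alone). That list nevertheless passed as a set with a median of 0.07 (camera adjusted p = 3.53e-05, but adjusted p = 0.541 with an estimated correlation and 0.0810 with the gene length trend removed). Of the 77 ribosomal protein genes 0 passed, with 2 higher and 2 lower at an unadjusted p under 0.05 and 1 called by DESeq2, and their median was 0.01 (camera adjusted p = 0.551). Transmitter synthesis and transport genes passed as a set (median -0.12, camera adjusted p = 0.00766, but adjusted p = 0.541 with an estimated correlation), although not without larval control replicate 2 (0.0998). In all, 7 lists passed by camera. The others were glycolysis and nuclear oxidative phosphorylation genes (lower), and transmitter receptor and beat and side genes (higher). Each of these was lost in at least 1 fit without 1 library.

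**Figure D3:**
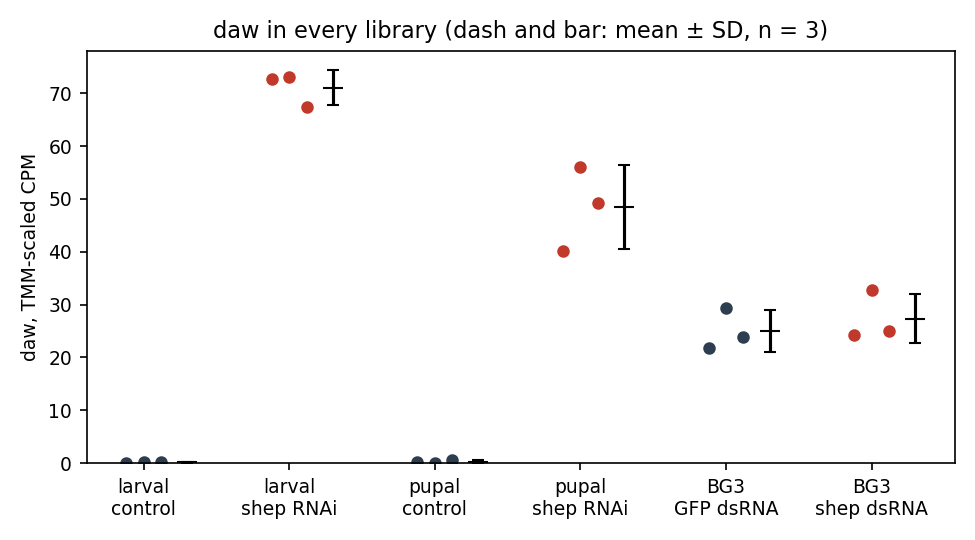
daw in each library, in TMM-scaled CPM on a linear axis from 0; points are libraries, and the dash and bar are the mean and SD of the 3. Neuron controls lie near 0, neuron RNAi libraries average 71.1 (larval) and 48.5 CPM (pupal), and BG3 cells average 25.0 CPM with GFP dsRNA and 27.3 CPM with shep dsRNA.

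To ask which responses differed between stages, the pupal response was tested against the larval one. Ribosomal protein genes had a lower response in pupal than in larval neurons, with 7 of 77 past the threshold for the difference (46 adjusted over the list alone) and a median difference of -0.35 (camera adjusted p = 2.94e-25, but adjusted p = 0.341 with an estimated correlation). ChAT (-0.77, SE 0.12), the vesicular glutamate transporter gene VGlut (-0.66, SE 0.12), Rop (-0.65, SE 0.12), EndoB (-0.68, SE 0.14) and Serinc (-0.70, SE 0.11) had responses that were more negative in pupae. sals (1.66, SE 0.31), BckdhB (1.53, SE 0.31), Drep3 (0.98, SE 0.19) and the actin-bundling gene sn (0.82, SE 0.13) had more positive ones. In all 32 of 8784 genes differed by edgeR at an adjusted p of 0.05, 9 with a more positive and 23 with a more negative pupal response. As sets, synaptic vesicle and active zone genes (median difference -0.18, camera adjusted p = 5.83e-05), nuclear oxidative phosphorylation genes (-0.15, camera adjusted p = 1.33e-05) and neuropeptide genes (-0.64, camera adjusted p = 2.79e-05) also had lower pupal responses. With an estimated correlation their camera adjusted p were 0.380, 0.569 and 0.144. As single genes, 1 of 33, 0 of 73 and 0 of 18 passed edgeR's threshold for the difference. At an unadjusted p under 0.05, 10, 12 and 5 were lower and 0 higher. Genes of the mitochondrial genome had lower pupal responses as a set too (median difference -0.50, camera adjusted p = 0.00111, but adjusted p = 0.663 with an estimated correlation, 0.0652 without pupal RNAi replicate 1 and 0.229 without a filter on low counts). Of 16 of them 0 passed edgeR's threshold, with 4 lower at an unadjusted p under 0.05 and 3 called by DESeq2. Cell cycle genes had higher ones as a set (0.22, camera adjusted p = 0.0262, but adjusted p = 0.661 with an estimated correlation). Of 36 of them 0 passed, with 5 higher and 2 lower at an unadjusted p under 0.05. The cell cycle list did not pass without pupal RNAi replicate 2 (0.0514), larval RNAi replicate 1 (0.0915), pupal control replicate 2 (0.0720) or larval control replicate 1 (0.218). The count of 32 genes fell to 18 without pupal RNAi replicate 1, 15 without larval RNAi replicate 2 and 13 without larval control replicate 3, and rose to 51 without pupal control replicate 2 and 89 without larval control replicate 1. BckdhB, EndoB, Rop, VGlut and Drep3 were each lost in at least 1 of those settings or another without 1 library, whereas ChAT, Serinc, sn and sals were not. With DESeq2, sals, BckdhB and Drep3 were not called, nor were BckdhB and EndoB with limma-voom.

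Control neurons of both stages were compared as the reference for these responses. Pupal neurons held far more transcripts of mature neuronal function. The peptide receptor gene SIFaR rose from 2.93 ± 0.71 CPM in larvae to 1855 ± 163 CPM in pupae (log2 fold change 9.28, SE 0.15), the histamine-gated chloride channel gene ort by 9.23 (SE 0.19), the potassium channel gene slo by 6.72 (SE 0.12) and the neuropeptide gene sNPF by 7.21 (SE 0.15). Of 33 synaptic vesicle and active zone genes 32 rose and 1 fell, including Snap25 (5.04) and comt (4.84). Transmitter receptors (40 of 41 higher), voltage-gated channels (26 of 27 higher), transmitter synthesis and transport genes (17 of 17 higher), dpr and DIP surface proteins (30 of 31 higher), beat and side genes (21 of 21 higher), peptide processing and receptor genes (31 of 34 higher, 1 lower) and neuropeptides (14 of 18 higher, 3 lower) rose too. Glycolysis (15 of 15 higher) and nuclear oxidative phosphorylation genes (70 of 73 higher, 2 lower) followed. These counts were the same adjusted over each list alone. Among falls, CPM of the neuroblast gene ase went from 97.9 ± 13.3 to 0.65 ± 0.48 (log2 fold change -7.20, SE 0.23), and the mitotic genes stg (-7.50), Incenp (-7.27) and CycB3 (-5.62), the Hox gene Antp (-6.69) and the temporal factor genes Syp (-3.04) and br (-3.12) fell.

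Neuroblast markers (15 of 16 lower), cell cycle genes (33 of 36 lower, 1 higher), proteasome genes (30 of 31 lower), Hox genes (10 of 11 lower, 1 higher), temporal identity genes (14 of 20 lower, 4 higher) and insulator and chromatin genes (24 of 30 lower, 3 higher) were lower in pupal neurons, again with the same counts adjusted over each list alone. All 77 ribosomal protein genes were lower, with a median of -1.78. The lists named here passed camera (adjusted p from 1.27e-14 for ribosomal proteins to 0.0224 for temporal identity), and with an estimated correlation only synaptic vesicle, beat and side, and peptide processing and receptor genes held, each at an adjusted p = 0.0323. Glial markers went both ways, with 9 of 20 higher and 9 lower, the same adjusted over the list alone (camera adjusted p = 0.843). The glutamate transporter gene Eaat1 rose from 30.8 ± 7.30 to 737 ± 26.4 CPM, whereas repo went from 8.38 ± 2.58 to 0.94 ± 0.36 CPM (SD, n = 3), and the log2 level of roX1 fell by 5.69 (SE 0.22), while elav fell by 1.20 on the log2 scale (SE 0.09). By edgeR 7315 of 8784 genes passed, 3428 higher and 3887 lower in pupae, and the median log2 fold change of all genes was -0.17. TMM scaling takes most genes as unchanged, which these calls do not bear out. The balance of rises and falls, and modest changes such as that of elav, therefore rest on the scaling.

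The response of BG3 cells to shep dsRNA was measured in the same way. Their summed neuron markers were low, at 482 CPM with GFP dsRNA against 55083 in pupal and 18235 in larval control neurons. Summed hemocyte markers were 8303 CPM, against 422 and 155. Neurons and BG3 cells were scaled apart. Wnt4, a secreted signalling protein gene, rose from 14.1 ± 3.03 to 29.1 ± 1.72 CPM (SD, n = 3; log2 fold change 1.03, SE 0.16), stv, a co-chaperone gene, rose by 1.09 (SE 0.17), and fj, a Golgi kinase gene of planar polarity, by 0.97 (SE 0.13). Their calls did not pass with DESeq2, nor did that of ssp6 (1.19), which was also lost without GFP dsRNA replicate 1, shep dsRNA replicate 1 or shep dsRNA replicate 3. Serinc, chosen after its values were seen, fell here too (-0.81, SE 0.09). Among the largest falls were snoRNA:Psi18S-1854b (-1.52) and snoRNA:Psi18S-1854c (-1.18), related copies; neither passed with DESeq2. Of 6816 genes tested, 369 passed an edgeR adjusted p of 0.05, with 228 higher and 141 lower. Of all tested genes, 23.6% had no overlap between the groups (chance gives 10%). Of the 20 genes named by rule, 6 were called in every fit without 1 library: shep, CG1273, Wnt4, stv, fj and snoRNA:Psi18S-1854b. Of the 20, only shep was called with DESeq2. The count fell to 170 and 221 without GFP dsRNA replicates 1 and 3, to 133, 164 and 154 without shep dsRNA replicates 1, 2 and 3, and to 115 when the BG3 libraries were fitted together with the neurons.

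In BG3 cells, 8 of 46 axon guidance and adhesion genes rose (13 higher and 2 lower adjusted over the list alone), with kirre (0.55), Wnt4 and the netrin receptor gene fra (0.39) at the smallest p values (camera adjusted p = 1.02e-04, but adjusted p = 0.487 with an estimated correlation and 0.0624 with the gene length trend removed). Of 21 genes of the mitochondrial genome 4 fell (9 adjusted over the list alone), led by mt:srRNA (-0.84) and mt:ND6 (-0.89), the latter not called without shep dsRNA replicate 1 (camera adjusted p = 1.46e-08, but adjusted p = 0.487 with an estimated correlation). The share of counts on the mitochondrial genome was 12.7% to 17.7% in GFP dsRNA and 7.53% to 10.1% in shep dsRNA libraries. Ribosomal protein genes were lower in 3 of 76 cases (11 adjusted over the list alone; RpL24 -0.83, RpL28 -0.32, RpS4 -0.30), and the set passed (camera adjusted p = 0.00574, but adjusted p = 0.674 with an estimated correlation). It did not pass without GFP dsRNA replicate 2 (0.871), without shep dsRNA replicate 3 (0.0590) or with the gene length trend removed (0.273), where however 9 of 76 were called lower. Each of the 3 calls was lost without at least 1 library. The JNK phosphatase gene puc (0.65) and the ecdysone-list gene plum (0.43) rose and were called in every fit without 1 library. Temporal identity genes passed as a set with 2 of 5 higher (4 adjusted over the list alone; camera adjusted p = 0.0121, but adjusted p = 0.487 with an estimated correlation, 0.0510 without shep dsRNA replicate 1, 0.417 without a filter on low counts and 0.215 with the gene length trend removed). With that trend removed, 6 of the 7 lists that passed in BG3 cells did not pass, all but the mitochondrial genome.

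Overlaps were counted to see whether the same genes responded in the 3 settings. Pupal and larval neurons shared 12 calls, 4 higher in both against 0.52 expected of independent lists (Fisher's exact adjusted p = 0.00349) and 8 lower in both against 0.71 (adjusted p = 5.89e-07). Besides shep these were daw, ftz, bark and CG30419, which rose, and nompA, frj, CG10444, Atox1, dachs, lute and lncRNA:CR45625, which fell. Summed counts of ftz were 3 and 61 in pupal control and RNAi libraries and 21 and 164 in larval ones, and those of nompA were 67 and 2 and then 68 and 6. Pupal neurons and BG3 cells shared 38 genes higher in both against 7.16 expected (Fisher's exact adjusted p = 5.59e-17) and 28 lower in both against 5.73 (adjusted p = 6.41e-12). Members of the fixed lists among them included Wnt4, Fas2, Lac, plum, Eip93F, brat and E2f1 (higher) and Rop, Pgk, PyK, RpL24, RpL28 and RpS4 (lower). In BG3 cells, Fas2, Eip93F, brat, Rop, Pgk, PyK and the ribosomal protein genes lost their call in at least 1 fit without 1 library. In pupal neurons plum, brat and E2f1 did, while Wnt4, Fas2, RpL24 and RpS4 were not followed through those fits there, nor was Lac in BG3 cells. Calls shared by pupal and larval neurons fell to 5 without larval RNAi replicate 1. Those shared by pupal neurons and BG3 cells fell to 30 without pupal RNAi replicate 1, to 35 and 42 without pupal control replicates 1 and 3, to 28 and 43 without GFP dsRNA replicates 1 and 3, and to 22, 27 and 24 without shep dsRNA replicates 1, 2 and 3. Only shep was called in the same direction in all 3 settings. Across genes, Spearman's rho of the log2 fold changes was 0.228 for pupal with larval neurons, 0.301 for pupal neurons with BG3 cells and 0.241 for larval neurons with BG3 cells, with the caution that genes are not independent replicates. The first was 0.119 without larval control replicate 1, 0.104 with DESeq2 and 0.111 without a filter on low counts. The second was 0.110 with DESeq2 and 0.109 without a filter. DESeq2 was run without that filter too, so its values do not separate the tool from the filter.

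**Figure D4:**
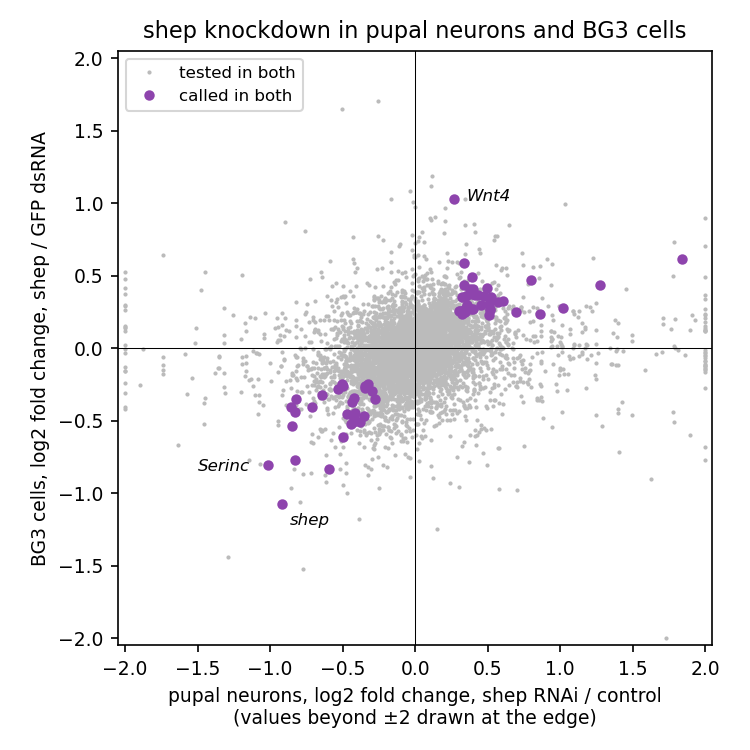
Log2 fold change on shep knockdown in pupal neurons (x axis) and BG3 cells (y axis) for the 6415 genes tested in both, with values beyond 2 drawn at the edge and the genes called in both in purple. The purple genes lie in the quadrants of shared direction, 38 higher and 28 lower in both, with shep and Serinc among the falls.

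The pupal RNAi response was set against the change from larva to pupa. Of the genes called in both comparisons, 258 rose during development and fell on RNAi (143 expected of independent lists), 117 rose in both (119 expected), 157 fell during development and rose on RNAi (135 expected) and 90 fell in both (162 expected). Synaptic genes such as Rop and comt, transmitter genes such as ChAT, and glycolysis genes such as Gapdh2 were of the first kind, while the 40 ribosomal protein genes that fell on RNAi also fell during development. Because both comparisons use the pupal controls, unchanged RNAi groups were simulated against them. Pearson's r across genes was -0.16, against a mean of -0.08 (-0.13 to -0.03 in 50 draws) with no effect, and the covariance was -0.218 against -0.0885, a difference of -0.13. Without pupal control replicates 1, 2 or 3 the observed covariance was -0.414, -0.340 and -0.419, and without the other libraries its weakest value was -0.156. It was -0.151 with limma-voom and -0.103 with only the groups compared in the fit, the last inside the range simulated without an effect (-0.148 to -0.0297). The simulation was made for the main setting and not for these. The expected overlaps do not allow for the shared controls. The simulations do, for r and the covariance. They drew each gene independently, without trends that the genes of a library share, so their range may be too narrow. Because they held almost no RNAi calls (overlaps of 0.18 genes or fewer on average), they give no expectation for the overlaps counted above.

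Genes called higher on knockdown in pupal neurons and BG3 cells were longer than expression-matched genes. In pupal neurons the median gene length was 11344 bp for genes called higher (5049 bp in 10000 matched random sets, 95% of them between 4324 and 5889 bp) and 2766 bp for those called lower (4992 bp, 4412 to 5738 bp). In BG3 cells it was 9294 bp (5601 bp, 4677 to 6811 bp) and 2512.5 bp (3681.5 bp, 2977.5 to 4526 bp). In larval neurons the medians lay within the range of matched sets, at 5868 bp for the 15 genes called higher (1748 to 6828.5 bp) and 3422 bp for the 17 called lower (1734 to 5645 bp). Spearman's rho between log2 fold change and exonic length, across genes, was 0.158 in pupal neurons, 0.159 in larval neurons and 0.245 in BG3 cells, and the last was 0.075 without GFP dsRNA replicate 2. By chromosome arm, the 17 genes called lower in larval neurons included 9 on 2R (Fisher's exact adjusted p = 0.0441), and genes called higher in pupal than larval control neurons included 60 of the 91 tested on chromosome 4 (adjusted p = 1.36e-05). Neighbouring genes called in the same direction on shep RNAi in pupal neurons formed 34 pairs against 25.4 with permuted calls (1-sided permutation p = 0.0532, adjusted p = 0.133). In BG3 cells there were 11 pairs against 10.1, and in larval neurons and for the difference 0. Only the comparison of pupal with larval controls, which involves no knockdown, passed, with 3535 pairs against 3002 (1-sided permutation p = 1e-04, adjusted p = 5e-04).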

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

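The tests of explanations and the splits in this part were chosen only after the results were seen; for the BG3 libraries at equal depth, the outcome each explanation calls for was written down before the test was run. The response to shep RNAi differed between pupal and larval neurons for 32 genes by a test of the difference itself. Of these, 9 had a more positive and 23 a more negative pupal response, and those taken by the rule for named genes are given here. As pupal minus larval log2 fold change, the positive differences among them were sals 1.66, BckdhB 1.53, CG34377 1.14, Drep3 0.98, sn 0.82, CG15725 0.65, GM130 0.63 and CG42232 0.58. The negative ones were CG6330 -0.78, ChAT -0.77, Sec71 -0.73, Serinc -0.70, EndoB -0.68, eIF3i -0.67, VGlut -0.66, RpS21 -0.66, Rop -0.65 and RpL37A -0.64. Of these 18 genes, 7 were called in every fit without 1 library (sals, CG34377, sn, CG6330, ChAT, Sec71 and Serinc) and 11 were lost in at least 1, GM130 in 9 of 12, EndoB in 8, CG42232 and RpL37A in 7 each and eIF3i in 6. Of 100 draws of the labels, 6 gave as many genes, the real one included, a share that does not exclude chance; the highest other draw gave 173 genes. All 6 kept the real pupal labels, which 7 of the 100 draws did, and so still carry the pupal response, while the other 93 draws gave 0 genes by edgeR. The share is therefore no test of the difference alone.

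Of the 10 splits of each 3 against 3 comparison, 1 gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The real count and the highest other were 672 and 0 for shep RNAi in pupal neurons, 32 and 1 in larval neurons, 7315 and 0 for pupal against larval controls, and 369 and 1 in BG3 cells.

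daw and 10 other genes besides shep were called in the same direction in pupal and larval neurons. In BG3 cells, where shep fell too, the log2 fold change of daw was 0.1167 (SE 0.15), against 7.37 in pupal neurons. But daw was already at 25.0 CPM in BG3 control cells and near 0 in neuron controls. A rise from near 0 could therefore not appear there, and daw alone does not decide whether shep loss acts alike in both. Of these 11 genes 7 were tested in BG3 cells, and 0 were called by edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05. Of the 7, 6 moved in the neuron direction, with a median of 0.1167 in that direction. The RNAi transgene, its insertion or the strain background would give a median this small, but a weak shared response is not excluded. The transgene may therefore account for these genes, and so may a response to shep that only neurons have. The design did not test between them because 1 RNAi genotype was used. BG3 cells had the low neuron markers given above, which limits them as a stand-in for neurons. Of the genes, daw, bark, frj and dachs lie on arm 2L, and nompA, CG10444 and CG30419 on 2R. The others lie on 3L, 3R and X. Whether location ties any of them to the insertion was not tested.

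Log2 fold changes on knockdown rose with exonic length across genes in pupal neurons (rho 0.158), larval neurons (0.159) and BG3 cells (0.245). With the length trend of each library removed, pupal neurons and BG3 cells shared 67 calls (13.3 expected), of which 43 were shared without the removal too, 2 genes were called in opposite directions, and the ribosomal protein fall in pupal neurons stayed past the threshold (camera adjusted p = 1.325e-17, median -0.33 before and -0.27 after), so the trend is not the whole cause of either. The axon guidance and adhesion rise may rest on it: its median went from 0.10 (quartiles 0.01 and 0.18) to 0.01 (quartiles -0.08 and 0.13) and its adjusted p to 0.3779, although a real change of long genes would be removed as well. Thinned to equal depth, the BG3 libraries gave a rho of 0.2404 with exonic length across genes. Random thinning leaves expected fold changes as they were, so this cannot show whether a difference tied to depth gave the trend. At full depth, rho was 0.075 without GFP dsRNA replicate 2. Whether the remaining trend is technical or a response to shep stays open.

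More genes were called on shep RNAi in pupal than in larval neurons. At the RNA level a weaker larval knockdown is argued against, because shep fell further in larvae (pupal minus larval 0.52, SE 0.15). That difference did not pass the threshold (edgeR adjusted p = 0.141), and the shep protein was not measured here. The median SE was 0.134 in larval and 0.161 in pupal neurons, but both came from 1 fit with a shared spread. They cannot show whether larval replicates varied more, so lower larval precision stays open. A single deviating library is argued against too: without pupal RNAi replicate 1 there were still 319 pupal calls, while larval calls reached at most 52 without 1 library (pupal control replicate 1). A stage-dependent response to shep is a candidate explanation, untested beyond the difference for the 32 genes above.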

How the results depend on the processing

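The settings with the length trend, the mitochondrial and rRNA genes or the depth changed were chosen after the data were seen. With no filter the counts were 76 (larval), 102 (difference), 27 (shared by pupal and larval neurons) and 114 (shared by neurons and BG3 cells), and the covariance of the pupal response with development was -0.653. With DESeq2, also run without a filter, the difference count was 116 and the covariance -0.338. With limma-voom the covariance was -0.151. With replicate number as a block, BG3 calls were 616 and those shared with neurons 127. Across genes, all 3 BG3 replicates correlated best with their own number (r 0.0410, 0.0969 and 0.111), as did replicates 1 and 2 between control stages (0.159 and 0.119), but no replicate within the pupal or larval RNAi comparison. With BG3 cells and neurons in 1 fit, or only the groups compared, they were 115 and 23, and the covariance was -0.103. An adjusted p under 0.01 gave 269 (pupal), 15 (larval), 5 (difference), 118 (BG3), 5 (shared by pupal and larval) and 8 (shared with BG3). A 2-fold minimum gave 68, 12, 7, 15, 5 and 0 by edgeR. Without 1 library the counts ranged over 319 to 895 (pupal), 10 to 52 (larval), 13 to 89 (difference), 133 to 466 (BG3), 5 to 17 and 22 to 95 (shared), and the covariance over -0.419 to -0.156. With the length trend removed, the log2 fold changes between stages of shep (-0.38) and Dcr-2 (-0.10) reversed, and 75 stage calls changed direction. The oxidative phosphorylation list in BG3 cells had a camera adjusted p of 1.79e-04 to 0.962 without 1 library, reversed without GFP dsRNA replicate 2. The stricter threshold and the fold minimum pass fewer genes by construction; for the others the cause was not tested. Among named pupal genes, 8 lost their call with DESeq2, 10 with limma-voom and 3 with RLE size factors; in BG3 cells 29, 6 and 1 did. Whether depth limited the low-expressed genes most was not tested.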

Other observations

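Genes of other groups responded to shep RNAi in pupal neurons as single members of lists that did not pass as sets. The cell death gene rpr rose by 0.86 on the log2 scale (SE 0.15, edgeR adjusted p = 9.07e-04), and 2 of 14 apoptosis genes rose (3 adjusted over the list alone; camera adjusted p = 0.470). The Polycomb group gene Psc rose by 0.70 (SE 0.10), with 2 of 30 insulator and chromatin genes higher (2 adjusted over the list alone; camera adjusted p = 0.739). The RNA-binding protein gene Fmr1 rose by 0.45 (SE 0.09). Of 29 RNA-binding and splicing genes 4 rose and 1, the targeted gene shep itself, fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0907). Of 34 peptide processing and receptor genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median 0.15, camera adjusted p = 0.475), the falls including the peptide amidation gene Pal2 (-0.68, SE 0.08) and the prohormone convertase gene amon (-0.39, SE 0.08). Of 31 dpr and DIP genes of the cell surface 5 rose and 1, DIP-epsilon (-0.56, SE 0.09), fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.475). Of 31 heat shock and stress genes 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.223), among them the superoxide dismutase gene Sod1 (-0.40, SE 0.08). Of 31 proteasome genes 2 rose, among them Prosbeta4 (0.65, SE 0.15), and 1, Rpn3 (-0.64, SE 0.14), fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.206).

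Of the BG3 libraries, GFP dsRNA replicate 2 stood apart in gene length: Spearman's rho across genes, between the deviation from the mean of the BG3 libraries and exonic length, was -0.422. It was 0.0207 and 0.0627 in the other GFP dsRNA libraries and 0.162, -0.0353 and 0.304 in the shep dsRNA libraries.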
